A study of Tribolium castaneum with 2 samples.

How the data were processed

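RNA of red flour beetle (Tribolium castaneum) larvae was measured on 2 two-colour Agilent arrays of a custom design for this species. Per the labels, adult females were left naive, jabbed with sterile saline, or jabbed with heat-killed Bacillus thuringiensis, a bacterium that infects insects, and were then mated. Their offspring were collected 2.5 weeks later and jabbed with about 20 live cells of the same bacterium, and 15 larvae per maternal treatment were pooled 24 hours after that. Beetles were kept at 30 °C and about 70% humidity. On both arrays the Cy3 channel held the same RNA of larvae of naive mothers. The Cy5 channel held larvae of saline-treated mothers on 1 array ("saline") and larvae of mothers given the killed bacteria ("primed") on the other. The labels give 1 array per comparison and the dyes were not swapped, so there is no replicate: no p-value or standard error was computed, and differences are described by size. The number of arrays limits the precision.

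The authors deposited the scanner output of each array, made with Agilent Feature Extraction 9.5.3.1 per the submitters' processing notes. Per the file headers, it holds the mean intensity of each spot and the median intensity of its local background in each channel, processed intensities with background subtraction, spatial detrending and dye normalization by linear and LOWESS steps, and the log10 ratio of Cy5 over Cy3 of these processed intensities. The deposited series table holds the same log10 ratio, since its values lay within 0.005 of the scanner files' ratio at every spot; both of its columns have a median of 0. No other per-sample column was left unused.

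Intensities were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, fitted on all spots, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess with the 1417 control spots at weight 0. Control spots and spots flagged as non-uniform were then left out, and no spot was saturated. Spots of a probe were averaged, then the probes of a gene. Of 33172 probes 10631 were spotted 2 times, and 16585 of 16587 gene identifiers had 2 probes. A probe was used where every spot was well above background in at least 1 of the channels compared. The primed against saline difference is the difference between the log2 ratios of both arrays, which removes the naive RNA and any dye effect shared by the arrays. For the naive RNA, Cy3 signals were compared between arrays after loess and Aquantile scaling. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

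On data simulated from the Cy3 channel of the saline array, in which 200 of 10682 genes differed by known sizes, the step placed past 2-fold 87.9% of genes made 1.5 higher on the log2 scale, 97.0% of those made 2 higher and 100.0% of those made 3 higher. For genes made lower the shares were 66.7% at -1.5, 82.4% at -2 and 97.1% at -3. The median estimate for the last was -2.45, so the sizes of lower genes were understated in the simulation. The altered genes were drawn from those well above background in Cy3 on both arrays. Higher genes with a dim naive signal were thus not simulated, and the shares do not cover them. None of the 10482 unaltered genes passed 2-fold, but this does not measure false calls. The simulated noise was normal and drawn separately for each spot, with its spread set by the bulk of Cy3 differences between arrays. The measured Cy3 difference of the same RNA had wider tails. Its SD was 0.154 against 0.087 by the median absolute deviation, and 30 genes were at least 2-fold apart.

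Before the data were examined, a size of 2-fold (1 on the log2 scale) was fixed for counts, as was the rule for named genes. For each comparison these are the 12 highest and 12 lowest genes with an informative symbol that passed 2-fold with all probes on 1 side of 0, up to 2 genes per direction without a symbol, and up to 4 members of each gene list. The array files give identifiers without descriptions. Symbols were taken from the RefSeq table of assembly icTriCast1.1 where a synonym carries the identifier or its gene model number, and 58 of 16587 identifiers matched. This assumes that the gene model number is the number in the array identifier; the peptide encoded by the probe was looked at for 2 of the matches only (H115 and hsp68a), so the named genes rest on that assumption. The array's build is not given in the sources used here, so no coordinates are reported. Of 29 gene lists fixed in advance by name, 25 had search terms that matched none of these symbols or their synonyms, and are not described. Such a list can still have members with a symbol. HEX1B, HEX2 and HEX4 have symbols, but the terms of the storage protein list did not match them. The other lists (Toll and IMD pathway, cytochrome P450s, heat shock proteins, cuticle proteins) had 1 to 5 members.

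Because of that, 38 lists were added by a peptide motif encoded in the 60-base probe sequences, read in 3 forward frames, with the reverse strand as a measure of false matches. Of these, 30 were written after the files had been opened and before any ratio was seen, 7 after the first list values had been seen, and 1 (RR-2 type cuticle protein) after the ratios and probe sequences of the most different genes had been seen. Other motifs that had been drafted to match single genes already known to differ were dropped. Of the 38 motifs 22 matched at least 1 gene. A motif gives a class of encoded segment, not the name of a gene. A list's median is given with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays only. Alternatives were no background subtraction, an offset of 10, the Agilent processed signals, median centring without loess, no filter or a stricter filter on dim probes, the brightest probe of each gene, the series table, and for primed against saline the Cy5 signals alone.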

Results

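The arrays held 43803 spots for 16587 gene identifiers. The median Cy5 spot intensity was 276 on the saline array and 274 on the primed array, against median local backgrounds of 37 and 36.5. The Cy3 medians were 86.9 and 75.1. In Cy5, 70.2% of spots on the saline array and 71.7% on the primed array were well above background, and in Cy3 62.7% and 61.8%. Each group was 1 pool of larvae on 1 array, so none of the differences has a replicate check. The probe values given with a gene are those of its lowest and highest probe and show measurement error within an array, not variation among larvae.

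The naive RNA, hybridised to both arrays, gave a measure of the technical error of the Cy3 channel, which was the dimmer one. The loess correction of a spot depends on the mean signal of both channels. This measure can therefore also hold a part of the Cy5 difference between the arrays, and is not technical error alone. It does not hold the separate pooling and RNA preparation of the Cy5 samples. The Cy3 signal of the naive RNA differed between the arrays with an SD of 0.154 on the log2 scale over 10975 genes. Of these, 30 genes (0.273%) were at least 2-fold apart. The Cy5 signals of primed and saline larvae differed with an SD of 0.652 over 12602 genes, and 663 genes (5.26%) were at least 2-fold apart. The median SD between the probes of a gene was 0.0577 for saline against naive, 0.0578 for primed against naive and 0.0553 for primed against saline.

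**Figure D1:**
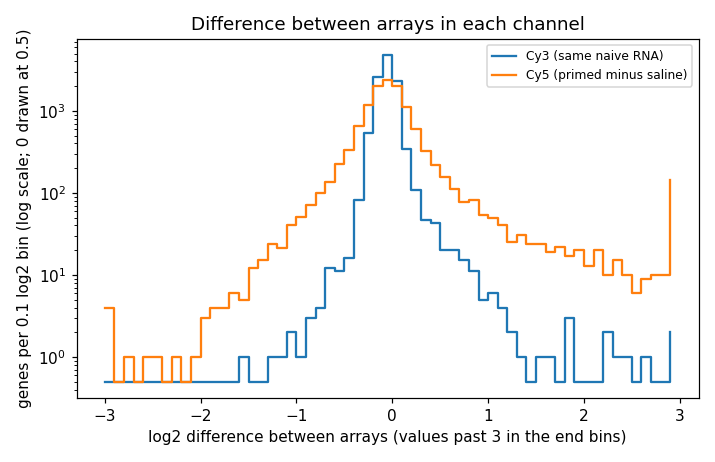
Genes per bin of the log2 difference between the primed and the saline array, for Cy3 (the same naive RNA) and Cy5 (primed minus saline larvae), with a log scale on the vertical axis. The Cy3 line is narrower (SD 0.154) than the Cy5 line (SD 0.652).

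The first comparison asks how infected larvae of saline-jabbed mothers differ from infected larvae of naive mothers. Hexamerins, storage proteins of insect larvae, stood on both sides. HEX4 (TC005375) was lower in saline larvae, with a log2 ratio of -2.96 (probes -2.99 and -2.92), while HEX1B (TC005377) was higher at 1.74 (probes 1.64 and 1.85) and HEX2 (TC006769) at 1.37 (probes 1.36 and 1.39). The cuticle gene Tc004500 (TC004500) was lower at -1.62 (probes -1.64 and -1.61), at -2.53 without loess and at -3.91 with the Agilent processed signals. Its saline signal was low, 6.01 on the log2 scale. CYP301B1 (TC007167), a cytochrome P450, was lower at -1.33 (probes -1.49 and -1.17) and at -2.38 with the Agilent signals. The saline signal of CYP301B1 was also low, 6.59 on the log2 scale. Ance-3 (TC002092) was lower at -1.21 (probes -1.29 and -1.14). Of 12158 measured genes, 188 were at least 2-fold higher and 360 at least 2-fold lower in saline larvae, and 535 of the 537 such genes with 2 probes had both on 1 side of 0. Among genes without a symbol, TC015793 (4.38) and TC015790 (4.29) were the highest, and both share a stretch of 20 bases with a probe of another gene; TC008769 (-7.55) and TC005225 (-6.31) were the lowest. The saline signal of TC005225 was low, 5.87 on the log2 scale, and with the Agilent signals it stood at -7.72, below TC008769 at -7.64. The higher genes made up 34.3% of these calls, 58.4% with the Agilent processed signals and 10.5% without loess.

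The gene lists held few measured members. Of 5 measured P450s, 1 was at least 2-fold lower and none higher, with a median of -0.43 (percentile 1.19). CYP6BQ9 stood at -0.54 from 1 probe, and passed 2-fold at -1.09 with the Agilent signals and -1.19 without loess. Its signals were low, 6.75 in naive and 6.47 in saline larvae on the log2 scale. It also shares a stretch of 20 bases with a probe of another gene. CYP346B2 stood at -0.43 and CYP9Z4 at 0.53. The 3 other genes whose probes encode a P450 haem-binding site, a class written before ratios were seen, had a median of 0.17 (percentile 80.6), and -0.19 without loess. The heat shock genes hsp68a (from 1 probe) and hsp68b stood at -0.09 and -0.12, a median of -0.11 (percentile 24.3). Without loess the median was -1.03, with hsp68a past 2-fold at -1.09. The signals of both genes were low, from 6.34 for hsp68a in saline larvae to 6.92 for hsp68b in naive larvae on the log2 scale. Tab2, the measured member of the Toll and IMD list, stood at -0.21 (percentile 25.4), and at 0.02 without loess. Tc004500 was the cuticle list's measured member (percentile 0.26). Among classes read from the probe sequences, the 9 genes with a chitin-binding R&R segment, found in cuticle proteins, had a median of -0.56, at percentile 0.01 (-1.08 with the Agilent signals), with 3 at least 2-fold lower and 1 at least 2-fold higher. Both genes with alanine-proline repeats of cuticle proteins were lower, with a median of -2.96 (percentile 0.03). The 6 genes with a serpin signature, a protease inhibitor family, had a median of 0.50 (percentile 99.8) and none passed 2-fold; the motif also matched 2 genes on the reverse strand. The gene with a defensin segment (TC006250), a class of antimicrobial peptide, stood at 1.03 (percentile 97.9). Both genes with a histone signature were at least 2-fold higher, with a median of 1.62 (percentile 98.1), and share probe sequence with other genes.

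The primed against naive comparison asks the same of larvae whose mothers had met killed bacteria. Tc004500 was higher in primed larvae at 2.01 (probes 1.94 and 2.07), as was HEX4 at 1.16 (probes 1.13 and 1.19). P76 (TC007017) was lower at -1.10 (probes -1.14 and -1.05), and short of 2-fold at -0.76 without loess. HEX1B stood at 0.52 and HEX2 at 0.26. Of 12347 measured genes, 349 were at least 2-fold higher and 85 at least 2-fold lower, and 428 of the 429 such genes with 2 probes had both on 1 side of 0. TC012820 (7.12) and TC012822 (5.90) were the highest genes without a symbol, and TC008769 (-4.98) and TC005624 (-4.77) the lowest. With the Agilent signals the first pair stood at 8.67 and 7.13, and TC005624 at -5.58 lay below TC008769 at -4.98. Higher genes made up 80.4% of these calls, and 12.6% without loess.

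With the main processing the 5 named P450s lay below 0 in primed larvae, with a median of -0.41 (percentile 0.10) and none past 2-fold. With the Agilent signals the median was -0.82. CYP6BQ9 passed 2-fold at -1.22 with the Agilent signals and -1.24 without loess. The haem-binding class had a median of -0.01 (percentile 33.4), and 0.17 with the Agilent signals. CYP346B2 stood at -0.71, CYP6BQ9 at -0.44, CYP301B1 at -0.41 and CYP6BQ10 at -0.14. The heat shock genes hsp68b and hsp68a stood at 0.82 and 0.61, a median of 0.71 (percentile 97.6). Neither passed 2-fold, but hsp68b stood at 1.00 without background subtraction, and with the Agilent signals both passed, at 1.31 and 1.08. Without loess they stood at 0.35 and 0.02, a median of 0.19. The hsp68a value came from 1 probe, and was 0.33 without the filter on dim probes. Averaged over its probes, the hsp68a signal was low, 6.90 in primed and 6.57 in naive larvae on the log2 scale. Tab2 stood at -0.23 (percentile 18.2), and at 0.01 without loess. Tc004500 lay at percentile 96.0 of random single genes. The 9 genes with an R&R segment had a median of -0.22 (percentile 0.98), and -0.59 with the Agilent signals, with 1 at least 2-fold lower. Both alanine-proline repeat genes lay below 0, with a median of -0.89 (percentile 0.49) and 1 at least 2-fold lower. The serpin class had a median of 0.14 (percentile 85.6), the defensin segment gene stood at -0.46 (percentile 8.74), and the histone class was higher with a median of 1.80 (percentile 97.9).

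**Figure D2:**
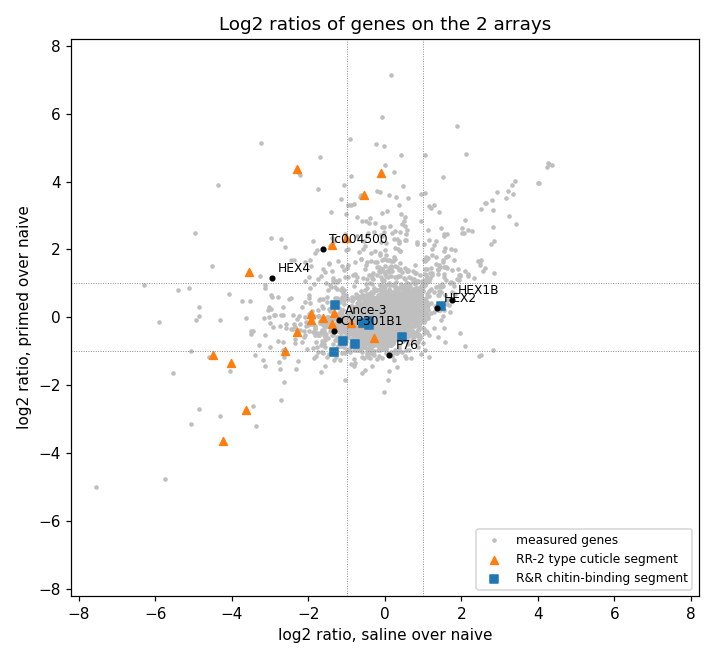
Log2 ratio of each measured gene in saline over naive larvae (horizontal) and primed over naive larvae (vertical). Squares are genes with an R&R cuticle segment, triangles genes with an RR-2 type segment (a class added after the ratios were seen), and black points named genes. HEX4 and Tc004500 lie at negative saline and positive primed ratios, and dotted lines mark 2-fold.

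Primed and saline larvae were compared directly to set the maternal bacterial dose apart from the jab. HEX4 was higher in primed larvae at 4.12 (probes 4.06 and 4.18), and Tc004500 at 3.63 (probes 3.59 and 3.67). With the Agilent signals HEX4 stood at 4.13 and Tc004500 at 6.39, so their order depends on the processing. Tc004500 was at 4.26 without background subtraction and 4.56 without loess, and its saline signal was low, 6.01 on the log2 scale. Ance-3 was higher at 1.12 (probes 1.01 and 1.23). HEX1B was lower at -1.22 (probes -1.23 and -1.21), HEX2 at -1.11 (probes -1.28 and -0.94; -0.96 with the Agilent signals and -0.94 with the brightest probe, short of 2-fold), P76 at -1.21 (probes -1.27 and -1.15) and H115 (TC010934) at -1.30 (probes -1.32 and -1.28). The probe of H115 encodes a C-terminal segment of the trypsin-like protease class. Of 12602 measured genes, 506 were at least 2-fold higher and 121 at least 2-fold lower in primed larvae, and 616 of the 621 such genes with 2 probes had both on 1 side of 0. TC002836 (8.37) and TC002831 (8.25) were the highest genes without a symbol; their saline signals were low, 6.01 and 5.78 on the log2 scale, and the Agilent signals gave 10.43 and 10.41. The lowest were TC006657 (-3.79; -4.92 with the Agilent signals) and TC006158 (-3.62). Higher genes made up 80.7% of these calls, and 67.3% with the Agilent processed signals.

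In this comparison hsp68b stood at 0.94 and hsp68a, from 1 probe, at 0.70, with a median of 0.82 (percentile 95.3). Both passed 2-fold with the Agilent signals at 1.74 and 1.33 and without loess at 1.33 and 1.11. Without background subtraction hsp68b passed at 1.19. TC009571, which shares with hsp68a an encoded C terminus of cytosolic HSP70 or HSP90, stood at -0.46. That class was added after the first list values were seen. Against naive TC009571 stood at 0.66 in saline and 0.20 in primed larvae. The named P450s had a median of -0.22 (percentile 2.43), with none past 2-fold, from CYP9Z4 at -0.65 to CYP301B1 at 0.92, with CYP346B2 at -0.29 and CYP6BQ10 at -0.22. CYP301B1 passed it at 1.10 without background subtraction, 1.46 with the Agilent signals, 1.03 without loess and 1.05 with the brightest probe. The haem-binding class had a median of -0.42 (percentile 0.53). Tab2 stood at -0.02 (percentile 41.9). Tc004500 lay at percentile 98.7. The R&R class had a median of 0.31 (percentile 99.7), with 1 gene at least 2-fold higher and 2 at least 2-fold lower. Both alanine-proline repeat genes were at least 2-fold higher, with a median of 2.07 (percentile 98.5). The serpin class had a median of -0.22 (percentile 2.46), and the defensin segment gene was lower at -1.49 (percentile 1.30). The histone class had a median of 0.17 (percentile 73.6), and -0.01 without loess.

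**Figure D3:**
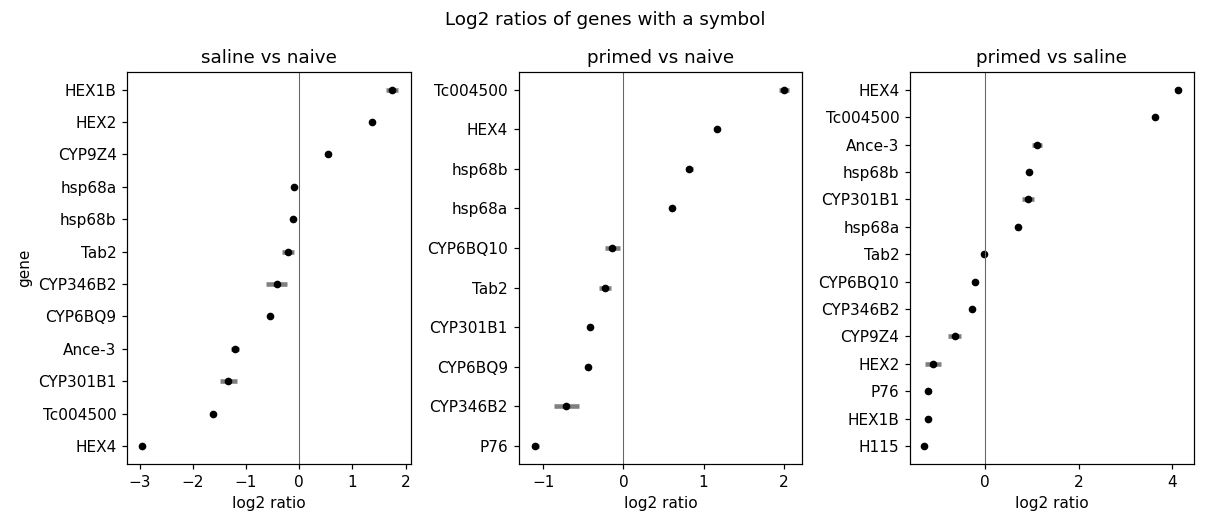
Log2 ratios of the named genes with a symbol in each comparison (horizontal axis, first group over second). Points are gene means and bars run from the lowest to the highest probe; the bars do not show variation among larvae. HEX4 runs from -2.96 in saline against naive to 4.12 in primed against saline.

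Across 11897 genes measured on both arrays, the log2 ratios had a Pearson correlation of 0.318 (Spearman 0.475) and a covariance of 0.0830; genes are not independent replicates. Simulated unchanged groups that share 1 naive pool gave a correlation of 0.50 and a covariance of 0.182, with each pool's spread taken from the primed minus saline difference. On both arrays 111 genes were at least 2-fold higher and 40 at least 2-fold lower than naive, where independent lists would share 5.31 and 2.57 and the simulated groups shared 167 and 168. The simulated correlation was fixed by design, since pools of equal spread give 0.50 whatever the size of that spread. The spread also holds any effect of the mother's treatment, which enlarges the simulated covariance and shared counts. The simulated values therefore set no bound on what a shared naive pool gives by itself. Part of the overlap may come from the shared pool. Without loess the observed correlation was 0.601, and no simulation was run at that setting.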

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

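The opposite directions below were not tested, since each group is 1 pool; the tests of explanations were fixed before their own values were seen, except the storage-protein value and the count of shared genes.

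Saline and primed larvae stood on opposite sides of naive larvae for a set of genes. Of these, 57 genes were at least 2-fold lower in saline and at least 2-fold higher in primed larvae, and 3 the reverse. The numbers that independent lists would share were not computed for these opposite directions. HEX4 and Tc004500 were among the 57, with primed minus saline differences of 4.12 and 3.63 (4.13 and 6.39 with the Agilent signals).

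The first pattern is that 29 genes whose probes encode a cuticle segment (R&R or RR-2 type) had a median primed minus saline log2 difference of 1.44, with 16 at least 2-fold higher and 2 at least 2-fold lower. The pattern rests on the 20 RR-2 genes, a motif written after the ratios were seen (median 1.84, 15 higher and 0 lower), while the 9 R&R genes, fixed before, had a median of 0.31 with 1 higher and 2 lower, so the size of the pattern is not independent evidence. Noise of hybridization or array position is argued against by the same genes' Cy3 signals, which differed between arrays by a median of 0.10. Reading of 1 transcript by probes that share an exact stretch of 20 bases is argued against by the 23 members without such a match. Their median was also 1.44. Probes that are alike but share no such stretch were not tested. Probes were compared with probes only, so binding of a probe to the rest of a related gene's transcript was not tested. Pools taken at different points of the moulting cycle may account for the pattern. This cannot be told apart from an effect of the mother's treatment, saline or killed bacteria, which stays open and untested. Against naive larvae, the RR-2 genes had a median of -1.77 in saline and -0.12 in primed larvae. The R&R genes had medians of -0.56 and -0.22. The medians of both classes thus lay further from naive in saline larvae. The labels give no stage and each group is 1 pool. The 3 hexamerin genes, taken by symbol, had a median of -1.11 while ranging from -1.22 to 4.12.

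The second pattern is that 151 genes were at least 2-fold from naive in the same direction on both arrays. Dye bias of single probe sequences is argued against: of 296 picks by 1 probe of a gene, the other probe of different sequence passed 2-fold the same way on both arrays in 83.8%. A gene whose probes both passed was counted once for each probe, so the share per gene is lower. The naive pool itself, or a dye effect of the labelled transcript, cannot be told apart from an effect of jabbing the mother, because 1 naive pool and 1 dye orientation served both arrays.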

How the results depend on the processing

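No paired analysis was possible because each group has 1 array. Alternatives beyond those planned were chosen after seeing the data: all for the correlation and for the naive RNA, and the Agilent signals joined with the strict filter. Counts stayed within 1.5 times under no background subtraction, an offset of 10, either filter on dim probes, the brightest probe, and Cy5 alone for primed against saline. With the Agilent processed signals the counts higher and lower were 803 and 571 for saline against naive, 980 and 223 for primed against naive, and 936 and 454 for primed against saline; the series table gave 805 and 571, 983 and 223, and 938 and 456. The Agilent signals with every channel well above background gave 314 and 541 for saline against naive, 228 lower for primed against naive, where 62.9% of calls were higher, and 367 lower for primed against saline, where 66.7% were. Without loess 298 and 2538 genes passed for saline against naive, 2539 were lower for primed against naive and 189 lower for primed against saline, and the median of all genes moved to -0.10 and -0.12 against naive. The cause was not tested. The correlation was 0.314 without background subtraction, 0.312 at the offset of 10, 0.346 with the Agilent signals and with the series table, 0.601 without loess, 0.311 without the filter and 0.340 with every channel well above background. The naive RNA had 18 genes at least 2-fold apart with the strict filter and 19 without a filter. No named gene past 2-fold changed direction under the alternatives run for named genes, though P76 (primed against naive) and HEX2 (primed against saline) fell short of 2-fold under some. Of the alternative values of all named genes, list members not past 2-fold included, 174 moved by no more than the SD of the gene's probes and 114 by more. The hsp68a log2 ratio of primed over naive was 0.61 with normexp, 0.73 without background subtraction and 1.08 with the Agilent signals, whose dye normalization also differs. The same ratio was 0.33 without the filter on dim probes and 0.02 without loess.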

Other observations

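The RR-2 and trypsin-like classes and the test of neighbouring identifiers were chosen after ratios or list values were seen; the bound for the correlation without shared probes was set before its value was known.

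The RR-2 motif, written after the ratios were seen, is not independent evidence of direction. Its 20 genes, with no reverse-strand match, had a median log2 ratio of -1.77 in saline against naive (-2.47 with the Agilent signals), below every random list, with 15 at least 2-fold lower. In primed against naive the median was -0.12 (0.13 without loess), with 6 at least 2-fold higher and 4 at least 2-fold lower. In primed against saline it was 1.84, above every random list, with 15 at least 2-fold higher and 19 above 0. Probes of 5 of the 20 share 20 bases with another gene. TC000719, at 2.68 in primed against saline, is also 1 of the alanine-proline repeat genes above, so these classes overlap. The lowest member stood at -0.30 and the highest at 6.67.

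The 24 genes with a trypsin-like C-terminal segment, another motif added after the first list values were seen, had 3 reverse-strand matches. Their median was 0.31 in saline against naive (percentile 99.99), with 3 at least 2-fold higher and 2 lower, and 0.12 in primed against naive (percentile 93.4). Between primed and saline larvae the median was -0.05 (percentile 12.5), with 14 of the 24 below 0, 4 at least 2-fold higher and 2 at least 2-fold lower.

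Of the motif classes written before any ratio was seen and not described above, most held no gene past 2-fold in primed against saline. The 18 measured genes with a zinc-finger linker had a median of -0.02 (percentile 32.1), the 11 with an EF-hand loop 0.07 (percentile 84.1; just below 0 without loess) and the 6 with a homeobox helix 0.11 (percentile 90.9). The peritrophin-type motif is an exception, with 1 of 4 measured genes at least 2-fold higher and a median of 0.76 (1.25 with the Agilent signals and 0.21 without a filter on dim probes), but it matched 9 genes on the reverse strand against 6 on the coding strand, so its members are not separable from false matches.

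Genes with consecutive identifiers differed together. Over 10046 pairs, the primed minus saline values of neighbouring numbers correlated at 0.243, against at most 0.0260 in 100 permutations. In this comparison 18 runs of at least 3 consecutive numbers, the longest of 9, were at least 2-fold higher. Another 3 runs, the longest of 4, were at least 2-fold lower. In saline against naive 2 such runs were higher and 14 lower, and in primed against naive 11 and 0. An exact stretch of 15 bases shared between neighbours' probes is argued against as the whole cause, since without such pairs the correlation was 0.229. Probes that are alike but share no such stretch were left in. Probes were compared with probes only, so binding of a probe to the rest of a neighbour's transcript was not tested. Co-regulated gene clusters may account for the correlation, which was not tested because the identifiers were not placed on a genome here.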
